A study of Drosophila melanogaster with 4 samples.

How the data were processed

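The series profiled histone H4 acetylated on lysine 16 (H4K16ac) by chromatin immunoprecipitation and sequencing (ChIP-seq) in wild-type Oregon-R embryos of Drosophila melanogaster aged 14 to 16 h. GEO's labels list 4 samples, 2 ChIP replicates and 2 input replicates, where input is chromatin DNA sequenced without immunoprecipitation. The labels give the antibody as H4K16ac(M), and the meaning of the M is not given in the sources used here. Per the labels' protocols, embryos were fixed with formaldehyde before immunoprecipitation. Nothing in the labels says whether the replicates came from separate embryo collections, so the spread between them can be technical.

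Each ChIP replicate came with a deposited list of regions of significant enrichment, and a combined list served the whole series. Per the labels, the input of the same replicate number was the control for each replicate list. The authors' region caller, its threshold and the way the combined list was made are not given in the sources used here. Bowtie 0.12.7 is named in the submitters' processing notes. Per the file headers, coordinates are in FlyBase release 5, and they are printed here as deposited, counting from 1. The inputs are not analysed here as samples of their own. The files hold no read counts per library, so the depth of each sample is unknown, and no interval or detection limit that needs it was computed.

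Each region carries a single positive score in the deposited files, per the file headers without a stated unit. Scores were used to rank or filter regions within a list, and by rank between overlapping regions of the replicate lists. Their scale was examined in the values. Among replicate regions of up to 2 kb, the score minus the most frequent score of the list was log2 of a ratio of whole numbers no larger than 1000 for 100% of regions in each replicate list, within a relative tolerance of 1e-10. With base e instead of base 2 this held for 0.344% of replicate 1 regions and 2.30% of replicate 2 regions, which are those at the most frequent score itself. In the combined list, among regions of the same widths, 69.0% of scores fitted a ratio of whole numbers up to 1000 in base 2 and 0.556% in base e. Differences between scores of a replicate list are therefore read here on a log2 scale whose zero is unknown. For the combined list this reading is open for the remaining scores.

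Covered bases were counted once where regions overlapped. The main region set was the bases inside a region of both replicates. Each replicate, their union and the combined list were also used. Arm lengths came from the file headers. The covered percent of X was divided by that of the 4 autosomal arms 2L, 2R, 3L and 3R as a whole. For its test, the 5 major arms were joined into a circle and the region set was shifted along it by 10000 random offsets (two-sided), so that region widths and spacing were kept. For replicate overlap, replicate 2 was rotated within each arm, 10000 times for the Jaccard index (shared bases over bases in either list) and 1000 times for shares of regions (200 for shares at 50% overlap on X or autosomal arms alone), and the test was one-sided. An overlap of 1 base counted as shared. Widths and scores on X and autosomal arms were compared by rotating the arm labels along the genomic order of regions (two-sided, every distinct rotation or 10000 of them). Spearman correlations across regions or windows used 100000 permutations (two-sided). Such tests are permutation tests over positions in the genome. Regions and windows are not replicates, and with 2 ChIP replicates no exact test across replicates can pass a threshold of 0.05. The smallest p is 1e-04 with 10000 rotations, 0.001 with 1000, 0.005 with 200 and 1e-05 with 100000 permutations. Where every distinct rotation of the arm labels was used, it is 1 over the number of regions compared, so it differs between lists. Intervals at 95% for the ratio of X to autosomal coverage came from 10000 bootstrap resamples of 1-Mb blocks, and cover variation along the arms, not between replicates.

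The main tests, region sets and the rule for named regions were fixed before the data were examined. The separate values of replicate overlap and of the window correlation for X and for the autosomal arms were added after the data were seen. The planned placement of regions at promoters, in gene bodies, in exons or introns and in gene lists was not run, because the gene table at hand is in release 6 and coordinates were not converted between builds. The planned gene-only denominator of arm coverage was not run for the same reason. The fixed rule for this case names, by coordinates, the 5 widest regions found in both replicates on X and on the autosomal arms, the 5 highest scored regions of the combined list, and the densest and sparsest 1-Mb window of each major arm. Regions named outside this rule are said to have been chosen after their values were seen. Alternatives were the left-out replicates, other region sets, a score filter at the list median, a minimum width of 500 bp, merging of regions less than 1 kb apart, trimming of the longer list, other overlap requirements and other window sizes.

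The rotation tests were tested on simulated data, in which regions were placed independently and uniformly along the arms and widths were drawn independently. The called regions are clustered, so the error rates below may not hold for them. Of 200 simulated region sets with equal coverage of X and autosomal arms, 2.5% gave a p under 0.05, and planted ratios of 1.5, 2 and 4 came back as 1.50, 1.97 and 3.89. The test of overlap gave a p under 0.05 in 3% of 100 simulated pairs with no shared regions and in 100% of those sharing a fraction of 0.5 of their regions. The width test did so in 7% of 100 sets with equal widths and in 100% of sets with 1.5-fold wider regions on X. Computations used Python 3.11.15, NumPy 2.4.6 and SciPy 1.17.1, and plots used matplotlib 3.10.9.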

Results

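H4K16ac is the acetylation that MOF, the acetyltransferase of the male-specific lethal (MSL) dosage compensation complex, places on the X chromosome of males. MOF also acts at promoters on all chromosomes as part of the NSL complex. The mark was mapped in late wild-type embryos, 14 to 16 h old, whose sex the labels do not give. Replicate 1 held 3397 enriched regions over 11.2 Mb and replicate 2 held 2202 regions over 6.91 Mb. The combined list held 6550 regions over 17.9 Mb. Read depth is unknown for all 4 samples, and the values below come from the authors' called regions, not from read counts.

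The first comparison asked how the mark was divided between X and the autosomes. H4K16ac regions covered 27.9% ± 6.01 (SD, n = 2) of X and 2.74% ± 1.66 (SD, n = 2) of the autosomal arms 2L, 2R, 3L and 3R. Coverage of X was 32.1% in replicate 1 and 23.6% in replicate 2, against 3.91% and 1.57% of the autosomal arms. Bases found in both replicates made up 21.5% of X and 1.15% of the autosomal arms, a ratio of 18.6. X is 22.4 Mb of sequence against 96.6 Mb of autosomal arms, yet it held 64.1% of the enriched bases of replicate 1 and 76.6% of those of replicate 2. The gap between X and every autosomal arm exceeded the spread between replicates. The lowest X value, 23.6%, lay above the highest autosomal value, 4.84% of 2R in replicate 1.

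The excess on X was past the threshold in each replicate in the rotation permutation test. The ratio was 8.21 in replicate 1 (95% block bootstrap interval 7.18 to 9.58, permutation p = 0.0005) and 15.1 in replicate 2 (12.9 to 17.7, permutation p = 0.0002). For bases in both replicates it was 18.6 (15.9 to 22.3, permutation p = 0.0002). These p-values concern positions in the genome. Permuting the labels of the 5 arms cannot give a p below 0.2. The size of the ratio depended on the region set. It was 7.91 for bases in either replicate, 5.93 in the combined list and 8.21 without replicate 2. For bases in both lists it was 50.9 after replicate 1 was trimmed by score to the bases of replicate 2. With regions at or above the median score of their list it was 114.5. Autosomal regions score lower: in replicate 2 their upper quartile was 0.786, below the list median of 0.854. Both cuts by score therefore raise the ratio whatever the cause and are no support for it.

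**Figure D1:**
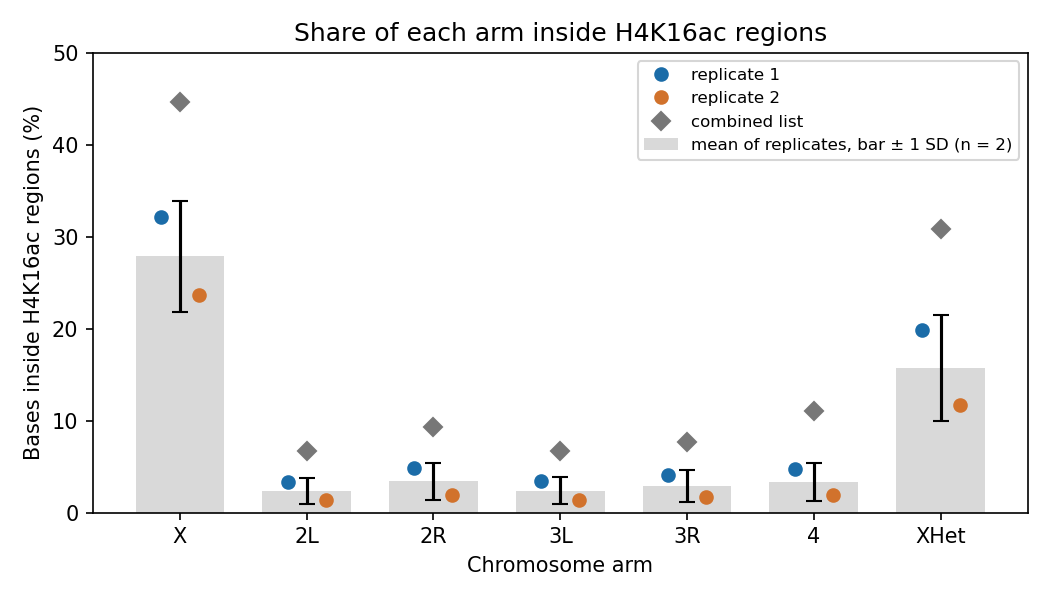
Percent of bases inside H4K16ac regions for the 5 major arms, chromosome 4 and the X heterochromatin scaffold XHet. Circles are the replicates, grey bars with error bars are their mean ± 1 SD (n = 2), and diamonds are the combined list; X (32.1% and 23.6%) and XHet (19.9% and 11.7%) stand above the autosomal arms, which do not exceed 4.84% in either replicate.

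Outside the 5 major arms, the small scaffold of X heterochromatin, XHet, was the most covered sequence, at 15.8% ± 5.77 (SD, n = 2), with 11.6% of its bases in both replicates. Chromosome 4, which is largely heterochromatic in character and bound by POF, was covered at 3.34% ± 2.05 (SD, n = 2), which is 1.22 times the autosomal arms in replicate 1 and 1.21 times in replicate 2. The ratio was 1.28 for bases in either replicate, 1.47 in the combined list and 0.997 for bases in both replicates, which form 10 regions on chromosome 4. The heterochromatin scaffolds of chromosomes 2 and 3 were covered less than the autosomal arms in both replicates. Their values ran from 0.757% of 3RHet to 1.79% of 3LHet in replicate 1, and from 0.266% of 2RHet to 0.964% of 3LHet in replicate 2. No region lay on YHet in either replicate, and the combined list had 2 regions there, over 0.712% of the scaffold. No list had a region on Uextra. Percents refer to full scaffold lengths, and unmappable sequence was not examined, so a low percent cannot be read as absence of the mark. These values carry no test, and XHet is 0.204 Mb long with 7 and 8 regions in the replicates. In replicate 1 the widest region outside the 5 major arms measured 30884 bp. By the covered totals and the minimum width it can lie only on XHet, so a single block made up most of that value. In replicate 2 the widest region outside the major arms measured 5543 bp. Replicate 1 alone covered 19.9% of XHet and 4.79% of chromosome 4, against 11.6% and 1.15% for bases in both replicates, so the values depend on the list.

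Regions on X were also wider. For regions found in both replicates, the median width was 2570 bp on X and 1686 bp on the autosomal arms, a ratio of 1.52. Regions of at least 10 kb occurred on X alone among the 5 major arms. There were 194 in replicate 1, 85 in replicate 2 and 261 in the combined list on X, and 0 on the autosomal arms in each of these lists. They held 48.3% of the covered bases of X in replicate 1 and 25.1% in replicate 2. The widest autosomal region measured 6968 bp in replicate 1 and 4135 bp in replicate 2, against 55984 bp and 43204 bp on X.

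The ratio of median widths was past the threshold in the rotation permutation test for bases in both replicates (p = 0.00053), in replicate 1 (1.30, p = 0.003), in replicate 2 (1.51, p = 0.00047) and in the combined list (1.13, p = 0.021). The values of 0.00053 and 0.00047 are the smallest that the numbers of regions allow. Merging regions less than 1 kb apart raised the ratio to 2.29. The lists hold no region narrower than a fixed minimum, which differs between the replicate lists and the combined list, so their medians measure widths above it. Regions found in both replicates are the stretches that the lists share, so this minimum does not bound their widths.

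**Figure D2:**
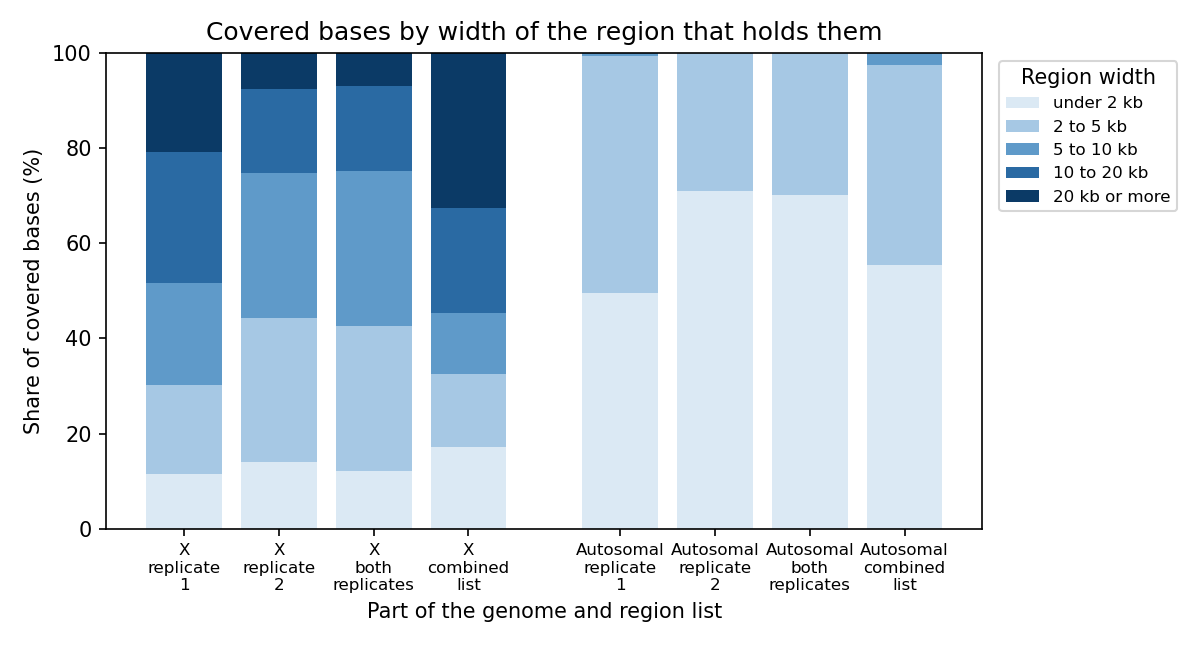
Share of covered bases (percent) that lie in regions of each width class, on X (left) and on the autosomal arms (right), for each replicate, for regions found in both and for the combined list. Classes of 10 kb or more hold 48.3% of X bases in replicate 1 and 25.1% in replicate 2, and no autosomal bases in any list.

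The 5 widest regions found in both replicates on X were long blocks of high score. The widest spanned 43.2 kb, from 1750423 to 1793626, and its scores lay at percentile 98.6 of replicate 1 and 97.3 of replicate 2. The next spanned 33.9 kb, from 6161880 to 6195769. A block of 29.7 kb ran from 6702818 to 6732502 and one of 27.1 kb from 2118879 to 2146007; the regions of replicate 1 there were 47.2 kb wide each. The fifth, from 15345095 to 15369471, spanned 24.4 kb. All 5 had replicate scores at percentile 95.3 or above of their list.

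On the autosomal arms the 5 widest were far narrower. They lay on 3R from 4475886 to 4479969 (4.08 kb), from 21503709 to 21507646 (3.94 kb) and from 11171099 to 11174876 (3.78 kb), and on 2R from 2548699 to 2552422 (3.72 kb) and from 18951975 to 18955544 (3.57 kb). Their scores were mixed. The 2R region from 2548699 scored 1.92 in replicate 1 and 1.91 in replicate 2, above percentile 99.8 of each list, whereas the 3R region from 11171099 was at percentile 59.8 in replicate 1 and 13.2 in replicate 2. Coordinates are in release 5, and the genes at these positions are not analysed here.

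The 5 highest scored regions of the combined list were of another kind. They scored 3.88 on X from 2725376 to 2726386, and 3.51 each on 2L from 12894474 to 12895474, on 2R from 19423654 to 19424654, on 3L from 19764390 to 19765392 and on 3LHet from 2226634 to 2228046. All 5 were 1.41 kb wide or less and none overlapped a region of either replicate. The score of 3.51 was shared by 9 regions, which were ordered here by position.

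Along the arms, X stood apart at the scale of 1 Mb. All 22 full 1-Mb windows of X were covered more than every one of the 95 autosomal windows, in replicate 1, in replicate 2 and for bases in both. On X, bases in both replicates ranged up to 34.5% of the window from 15 to 16 Mb and were lowest at 11.04% of the window from 3 to 4 Mb, with a median of 20.7%. On the autosomal arms the densest windows were 19 to 20 Mb of 2R (2.72%), 1 to 2 Mb of 3R (2.69%), 2 to 3 Mb of 2L (2.21%) and 21 to 22 Mb of 3L (2.03%). The sparsest were 7 to 8 Mb of 2L (0%), 13 to 14 Mb of 3L (0.144%), 16 to 17 Mb of 2R (0.338%) and 26 to 27 Mb of 3R (0.360%).

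The replicates ranked the windows alike. Spearman's rho across windows was 0.974 on X, 0.843 on the autosomal arms and 0.916 over all 117 windows (permutation p = 1e-05 for each, the smallest that 100000 permutations can give). Windows are not independent replicates, and the value over all arms includes the gap between X and the autosomes.

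**Figure D3:**
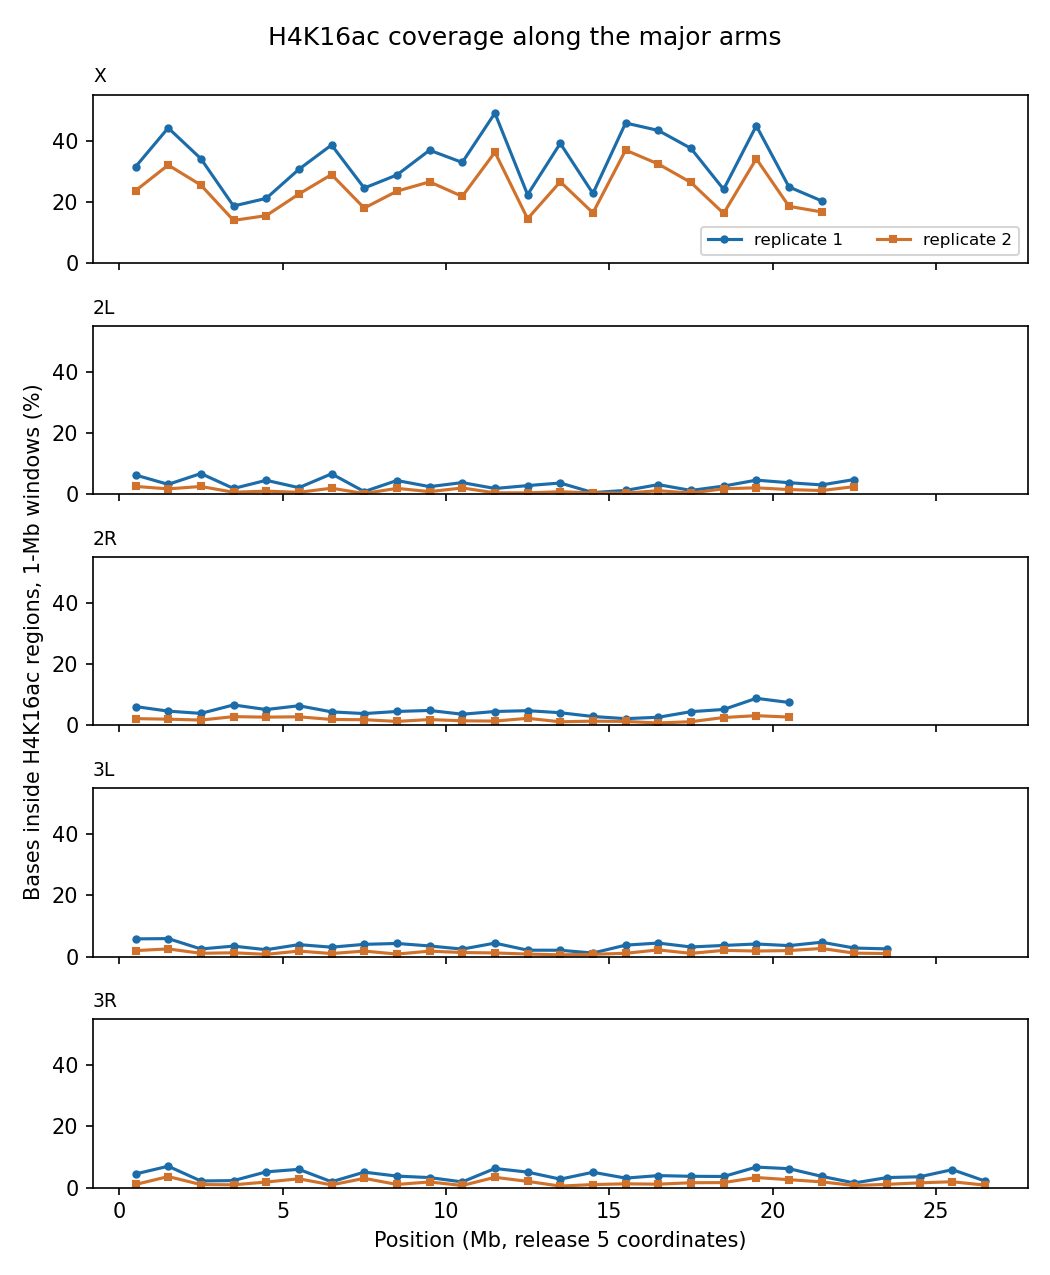
Percent of bases inside H4K16ac regions in 1-Mb windows (vertical axis) against position in Mb (horizontal axis) for X, 2L, 2R, 3L and 3R, with replicate 1 as circles and replicate 2 as squares. All 22 X windows lie above the 95 autosomal windows of the same replicate, and the profiles of the replicates on X run in parallel (rho = 0.974).

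Counted in bases, more of the mark was shared between replicates on X than on the autosomal arms. On X, 91.1% of the bases of replicate 2 lay inside regions of replicate 1, and 67.0% of those of replicate 1 inside replicate 2. On the autosomal arms the shares were 73.6% and 29.5%. The Jaccard index was 0.629 on X and 0.267 on the autosomal arms, and 0.496 over all sequence, where 6.01 Mb were shared. Replicate 1 had 2.22 times as many autosomal regions as replicate 2 (1908 against 860) and 1.07 times as many on X (1384 against 1290). Of the autosomal regions, 75.8% of replicate 2 touched replicate 1 and 33.9% of replicate 1 touched replicate 2. On X these shares were 87.8% and 58.2%. Rotated placements averaged 45.4% and 37.4% on X (permutation p = 0.002 for each). They averaged 7.31% and 3.35% on the autosomal arms (permutation p = 0.001 for each).

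Overlap exceeded that of rotated placements in each part of the genome. The rotation mean of the Jaccard index was 0.158 on X and 0.0116 on the autosomal arms (permutation p = 1e-04 for each, the smallest that the rotations can give). The index was 0.208 on chromosome 4 and 0.584 on XHet, against rotation means of 0.0141 and 0.0934. Whether X and autosomal arms differed in overlap was not tested, since a denser arm also overlaps more by chance. Taking regions at or above the median score of the whole list lowered the autosomal index to 0.117. That cut removed most autosomal regions, whose median was 0.570 against a cut of 0.644 in replicate 1. In replicate 2 their upper quartile was 0.786 against a cut of 0.854. No autosomal median was used, so poorer agreement of strong autosomal regions cannot be read from it. Asking for 50% of both regions lowered the share of replicate 2 regions found in replicate 1 from 82.7% to 50.7%. With that requirement the order of X and autosomes turned for replicate 2 regions, of which 40.2% on X and 67.7% on the autosomal arms were found in replicate 1, while for replicate 1 regions the shares were 37.4% and 30.5%.

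**Figure D4:**
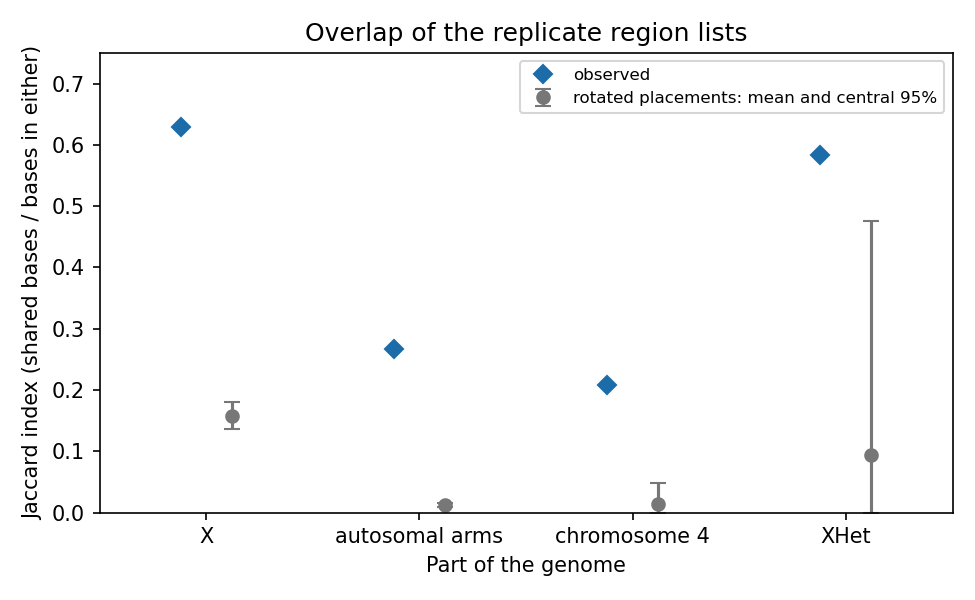
Jaccard index of the replicate region lists (shared bases over bases in either list) on X, the autosomal arms, chromosome 4 and XHet. Diamonds are observed values (0.629, 0.267, 0.208 and 0.584), and grey circles with bars are the mean and central 95% of rotated placements of replicate 2.

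Scores of overlapping regions were rank-correlated between replicates on X and, with a lower rho, on the autosomal arms. Across 761 overlapping pairs on X, Spearman's rho of the scores was 0.755, across 639 autosomal pairs it was 0.361, and across all 1428 pairs 0.768 (permutation p = 1e-05 for each). Regions are not independent replicates, and the value over all pairs includes the gap in scores between X and the autosomes. The pairs are regions called in both lists, so weak regions are missing from them. Over all regions, scores spread less on the autosomal arms than on X. Their SD was 0.154 against 0.214 in replicate 1 and 0.157 against 0.176 in replicate 2. Whether this lowers the autosomal rho was not tested.

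The combined list contained nearly all of each replicate list and much besides. It included 98.0% of the bases of replicate 1 and 97.7% of those of replicate 2. Of its own bases, 33.7% lay in both replicates, 32.1% in a single replicate and 34.2% in neither. On X, 48.3% lay in both and 24.5% in neither, and on the autosomal arms 15.3% and 45.8%. After merging of overlapping regions, 3310 of 6549 combined regions, 50.5% (95% Wilson interval 49.3 to 51.8, counting error only), touched no region of either replicate. This share depended on width, since the combined list holds regions narrower than any replicate region. Outside its 100 highest scored regions, 8.62% of 1950 such narrow regions overlapped a replicate region. Of 2326 others up to 2 kb 46.2% did, and of 2174 over 2 kb 90.9%. These are values with no test, since the files do not describe how the combined list was made from the replicates.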

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

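The windows and overlaps of X and autosomes taken apart, the comparison of 2R with other arms, trimming by number of regions and the combined list without its narrowest regions were chosen after the data were seen. The planned minimum width of 500 bp removed 0 regions, tests nothing and is not counted here. Of 74 other alternatives over all results, 57 had a test, and 54 of these kept the direction and the side of the threshold of the reported value. The other 3 concern 2R, covered 1.37 times as much as the other autosomal arms for bases in both replicates (rotation permutation p = 0.11): 1.32 without replicate 2 (p = 0.025), 1.32 for bases in either replicate (p = 0.029) and 1.32 in the combined list (p = 0.014). Adjusted over 4 arms by Benjamini-Hochberg, these rotation permutation p-values were 0.1, 0.12 and 0.056. With regions at or above the median score the 2R ratio was 2.10 (rotation permutation p = 0.054). The count of 54 includes the score filter and the trimmings of the X ratio. Autosomal regions score lower, so these raise the ratio of X to autosomal coverage whatever the cause and do not test it. That ratio ranged from 5.93 to 114.5, that of median widths from 1.13 to 2.29 and the Jaccard index over all sequence from 0.496 to 0.575. The index ranged from 0.620 to 0.674 on X and from 0.117 to 0.267 on the autosomal arms. Left-out replicates gave X ratios of 8.21 to 15.1 and width ratios of 1.30 to 1.51. Values without a test also moved. Chromosome 4 coverage, 1.15% in both replicates, ranged from 1.89% to 4.79% when a replicate was left out, was 5.53% for bases in either replicate and 11.1% in the combined list, and fell to 0.263% after trimming and 0% with regions at or above the median score. XHet, 11.6%, ranged from 11.7% to 19.9%, then 19.9% and 30.8%, and was 8.30% with regions at or above the median score. These sets are larger or smaller by construction. With combined regions at or above their median score, 46.8% of bases lay in both replicates, 29.3% in a single replicate and 23.9% in neither. Promoter, gene body, genic context and gene list results, their alternatives and the gene-only denominator were not run, since annotation of release 5 is not used here. No paired analysis was possible because the numbered inputs have no values of their own here, so ChIP and input cannot be compared. Read depth is unknown, so regions missing from a list are regions not called, and absence of the mark cannot be read from them.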

Other observations

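Tests in this part chosen after the results were seen are the whole-number ratios of scores, trimming by number of regions, the comparison of autosomal arms, the autosomal regions scored above X and the highest scored regions of the combined list. Called regions were clustered on X and on the autosomal arms. On X, 85 gaps of at least 50 kb separated the regions of replicate 1 and 89 those of replicate 2, where 1000 random placements of the same regions averaged 14.6 and 29.7 and did not exceed 26 and 43 (permutation p = 0.001, the smallest possible). The median gap on X was 2.53 kb in replicate 1. The longest stretch of X without a region of either replicate ran from 21500766 to 21845556 (344.8 kb), and the next from 7229048 to 7498833 (269.8 kb); the combined list covered 0.967% and 4.61% of them. On the autosomal arms 522 gaps of replicate 1 and 119 of replicate 2 were shorter than 5 kb, against averages of 189 and 38.5 in random placements and maxima of 227 and 54 (permutation p = 0.001). The 5 longest autosomal stretches without a region all lay on 2L between 11278901 and 17409963, the longest being 533.6 kb, of which the combined list covered 0.953%. Absence of the mark cannot be read from these stretches, and unmappable or gene-poor sequence was not examined.

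In each replicate a few autosomal regions scored above every region on X, although the autosomal median was lower; they were chosen after their values were seen. In replicate 1, where the highest X score was 1.47, these were 4 regions, on 2R from 2548648 to 2552482 (1.92), on 3R from 9842277 to 9845422 (1.89), and on 2R from 9887227 to 9889722 (1.499) and from 9911389 to 9913950 (1.49). In replicate 2, where the highest X score was 1.64, they were 3 regions, on 3R from 9842339 to 9845385 (2.04), and on 2R from 2548699 to 2552422 (1.91) and from 6158075 to 6160274 (1.66). Each overlapped a region of the other replicate. 2R was the most covered autosomal arm in each list, at 1.32 times the other autosomal arms in replicate 1 and 1.34 times in replicate 2, but no arm passed the adjustment over 4 arms (lowest Benjamini-Hochberg adjusted rotation permutation p = 0.1 and 0.24, and 0.056 in the combined list).

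Scores were higher on X, with medians of 0.771 against 0.570 in replicate 1 and 0.969 against 0.703 in replicate 2. The differences were 0.20 and 0.27 (rotation permutation p = 0.00091 and 0.00047, the latter the smallest possible). Wider regions on X could account for this if wide regions score higher. Among regions of up to 2 kb, whose median widths were 1537 and 1596 bp on X and autosomes in replicate 1, X still scored 0.131 higher in replicate 1 (permutation p = 0.0006) and 0.163 higher in replicate 2 (permutation p = 0.00088), each p being the smallest possible. Width therefore did not account for the whole difference. The sexes were not separated, so no biological explanation was tested.

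The ratio of X to autosomal coverage was 8.21 in replicate 1 and 15.1 in replicate 2. Whether the longer list of replicate 1, in bases or in number of regions, accounts for this stays open: kept from the highest score down to the bases of replicate 2 it gave 41.1, and kept to 2202 regions it gave 14.7. Autosomal regions score lower, so trimming by score raises the ratio whatever the cause, and the matchings gave different sizes. Of the 1261 autosomal regions of replicate 1 alone, 22.4% lay within 5 kb of a replicate 2 region. Rotations gave 10.7% on average and at most 15.5% (permutation p = 0.0001). This argues against random placement of all of these regions. Most of them lay farther away, so background calls among them stay open. Fewer reads behind replicate 2 may also contribute. Ratios of whole numbers up to 100 accounted for 68.2% of its scores among regions of up to 2 kb and for 35.9% in replicate 1. These ratios were taken to the most frequent score of each list. That score was held by 2.30% of such regions in replicate 2 and by 0.344% in replicate 1. The shares thus rest on unlike references and cannot settle the question. Embryo collection or antibody differences stay open and were not tested.

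Of the 100 highest scored regions of the combined list, 79 were at most 2 kb wide and 0 of these overlapped a replicate region, whereas all 21 wider ones did. Low overlap goes with narrow width in this list, so regions were compared within width classes: 0 of 68 top regions narrower than any replicate region overlapped a replicate region, against 8.62% of 1950 others as narrow. Windows with few reads may lie behind these narrow regions, since ratios of whole numbers up to 50 accounted for 76.5% of their scores and for 10.9% of those of the others. For the 21 wide regions the question stays open. Few reads called for a lower overlap than among other combined regions over 2 kb, which was not seen (100% against 90.9%). Whether overlap was higher cannot be told, since even 100% of 21 regions gives a one-sided exact binomial p of 0.135. Ratios up to 50 accounted for 9.52% of their scores against 3.40% (one-sided exact binomial p = 0.159). Of the 68 narrow regions 58.8% lay outside the 5 major arms, against 6.21% of the others, so repeated sequence stays open, as do the rules for merging replicates; neither was tested.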
